A study of Homo sapiens with 8 samples.

How the data were processed

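Total RNA from 8 human cell cultures was sequenced, from 4 NSCLC lines each grown alone or with CAFs. Per the labels' protocols, libraries were depleted of ribosomal RNA with a NEBNext kit and made with the MGIEasy directional kit, and were read on a DNBSEQ-G400RS sequencer with paired ends. Whether both reads of a pair were counted was not given in the sources used here. The authors deposited 1 gene table per library, with 54308 RefSeq genes. The genome build was GRCh38.p13 per the submitters' processing notes. The read mapper, the counting tool, the strand setting and any read filter were not given in the sources used here.

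Per the file headers, each deposited table gives read counts per gene in several classes, namely total gene reads, unique gene reads, exon reads, intron reads and reads across exon junctions. These are whole numbers without normalization. Total gene reads include intron reads, so a gene's count can move with the amount of unspliced RNA. The deposited TPM values are so named per the file headers, and served only for an alternative. The deposited RPKM values, per the file headers, were checked against the files and stand in a fixed proportion to exon reads per kilobase within each library. The files also hold columns with a fraction of reads per gene, per the file headers. RPKM and the fractions entered no comparison.

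All Y-linked genes, XIST and TSIX (581 genes) were left out, and 53727 genes remained. Each sample's group and line came from the labels. The labels give each line 1 library per condition, so the line pairs the libraries, and the 4 lines served as the replicates of the culture effect. In leave-out fits replicate 1 is PC9, 2 is H1299, 3 is H1975 and 4 is HCC827. Read totals over these genes were 36914351 to 65482310, at which 3 reads correspond to 0.0813 CPM in the shallowest library and 0.0458 CPM in the deepest.

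Genes with at least 10 total gene reads in at least 4 libraries were tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling, a robust quasi-likelihood fit of cell line plus culture, and Benjamini-Hochberg adjustment at 0.05. With 3 residual degrees of freedom per gene the test measures how far the lines disagree. A standard error was taken as the log2 fold change over the square root of the F statistic. Log2 ratios of a line were computed from CPM with a prior count of 3, and their mean and SD are over 4 lines. Single-line comparisons had no test. A gene was counted there when its log2 ratio was at least 2 in size and a library of the pair reached 1 CPM.

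The 32 gene lists were fixed before the data were examined, with 574 entries, of which 556 matched the tables by symbol and 18 by gene ID through a RefSeq table. They cover fibroblast identity, contractile myofibroblast and fibroblast-secreted genes, epithelial and lung lineage genes, mesenchymal transition, TGF-beta response, and the signalling, stress, metabolism, proliferation, adhesion and cell type lists that the results name. Lists with at least 5 tested members were tested with camera from limma 3.58.1 on log2 CPM, with a preset correlation of 0.01 and the same design. Camera with an estimated correlation and fry were run beside it. Camera sets a list against the other genes, and fry tests it against no change. The share of reads in the fibroblast identity list was compared by an exact two-sided sign-flip permutation over the lines, with exact binomial intervals at 95%. For each line, a list's median was set among 10000 random lists matched on mean expression.

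The genes to name were also fixed in advance. They were the 12 protein-coding genes with the largest log2 fold change in each direction among those past the threshold, with the same sign in all lines and a mean of at least 5 CPM, and where fewer than 5 qualified, the 5 with the smallest p, given as values. To these were added up to 4 members per list with the smallest p, the 5 highest and 5 lowest protein-coding genes per line with at least 10 CPM in a library, and 8 markers. Some genes that this rule selects are not reported here.

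The alternatives were scaling by RLE size factors, scaling without the fibroblast lists, DESeq2 1.42.0, limma-voom, no low-count filter, a minimum of 100 reads, no block for the line, unique gene reads, limma on log2 TPM with pseudocounts of 0.5 and 1, other priors and minimums in the single-line counts, and leaving out each line in turn. Exon reads alone were added after seeing the data. For co-culture against monoculture over 4 lines, the fit was tested on simulated counts of 21178 genes with the real library sizes and fitted dispersion. The genes changed had a mean of at least 100 reads. It called 96 of 100 genes changed by 4-fold and 99 of 100 changed by 16-fold, with 18 false calls. Camera called 0 of 32 lists when no list was changed. Those simulated genes vary independently, which the genes of a list do not. Figures were drawn with matplotlib 3.10.9.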

Results

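RNA was sequenced from 4 human non-small cell lung cancer (NSCLC) lines, each grown alone and grown with cancer-associated fibroblasts (CAFs), the activated fibroblasts of tumour stroma, for 48 h. PC9, H1975 and HCC827 are lung adenocarcinoma lines that carry activating EGFR mutations, and H1299 is a large cell carcinoma line that lacks p53. There were 8 libraries, 4 of monocultures and 4 of co-cultures, with 1 library per line and condition. The total of gene reads was 65482310 in the PC9 monoculture and 44163890 in its co-culture. It was 36914351 and 65048390 for H1299, 58940378 and 59827431 for H1975, and 54424720 and 53630373 for HCC827. The per-protocol source of RNA was the NSCLC cells, and whether CAFs were removed before extraction was not given in the sources used here. The share of reads in introns, with mitochondrial genes left out, was 15.8% and 13.1% in the PC9 monoculture and co-culture, 22.1% and 13.5% for H1299, 20.9% and 12.96% for H1975, and 16.8% and 22.5% for HCC827.

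The first question was how much fibroblast RNA the co-culture libraries held. Genes of fibroblast identity had a higher share of reads in all 4 co-cultures, and EPCAM differed little between the cultures of PC9, H1975 and HCC827. COL1A1, a chain of type I collagen, went from 58.4 to 349 CPM (read counts scaled to a common library size by TMM) in PC9, from 5.74 to 1021 in H1299, from 214 to 10080 in H1975 and from 36.7 to 1329 in HCC827. PDGFRB, the platelet-derived growth factor receptor of mesenchymal cells, went from 0.345 to 3.80 CPM in PC9, from 0.823 to 65.1 in H1299, from 6.41 to 387 in H1975 and from 0.265 to 46.1 in HCC827. COL3A1, a chain of type III collagen, was between 0.284 and 0.616 CPM in the monocultures and at 10.1 CPM in the co-culture of PC9, 124 in H1299, 968 in H1975 and 113 in HCC827. EPCAM, an epithelial adhesion molecule, was at 160 and 191 CPM in PC9, 111 and 108 in H1975 and 135 and 141 in HCC827, monoculture first, and under 1 CPM in both H1299 libraries. Not every epithelial marker was as steady. CDH1 went from 556 to 488.5 CPM in PC9, 565.5 to 430.7 in H1975 and 1256 to 793.5 in HCC827.

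The reads of the 24 genes in the fibroblast identity list made up 0.0317% of the gene reads of the PC9 monoculture (95% exact binomial interval 0.0313 to 0.0321) and 0.136% of its co-culture (0.135 to 0.137). The share went from 0.0325% (0.0319 to 0.0331) to 0.251% (0.250 to 0.252) in H1299, from 0.129% (0.128 to 0.130) to 2.05% (2.047 to 2.054) in H1975, and from 0.0173% (0.0169 to 0.0176) to 0.312% (0.311 to 0.314) in HCC827. That is 4.29-fold in PC9, 7.73-fold in H1299, 15.9-fold in H1975 and 18.1-fold in HCC827. The mean log2 change was 3.31 ± 0.97 (SD, n = 4 lines), higher in 4 of 4 lines, with p = 0.125 in an exact two-sided sign-flip permutation test, which is the smallest p that 4 pairs allow. Intervals of read counts here and below cover counting error only, and are too narrow even for that where reads were amplified from the same molecule. They hold no difference between cultures of the same line, which 1 library per condition cannot show. Bootstrap intervals further on resample the members of a list as if these were independent, and have the same limit.

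**Figure D1:**
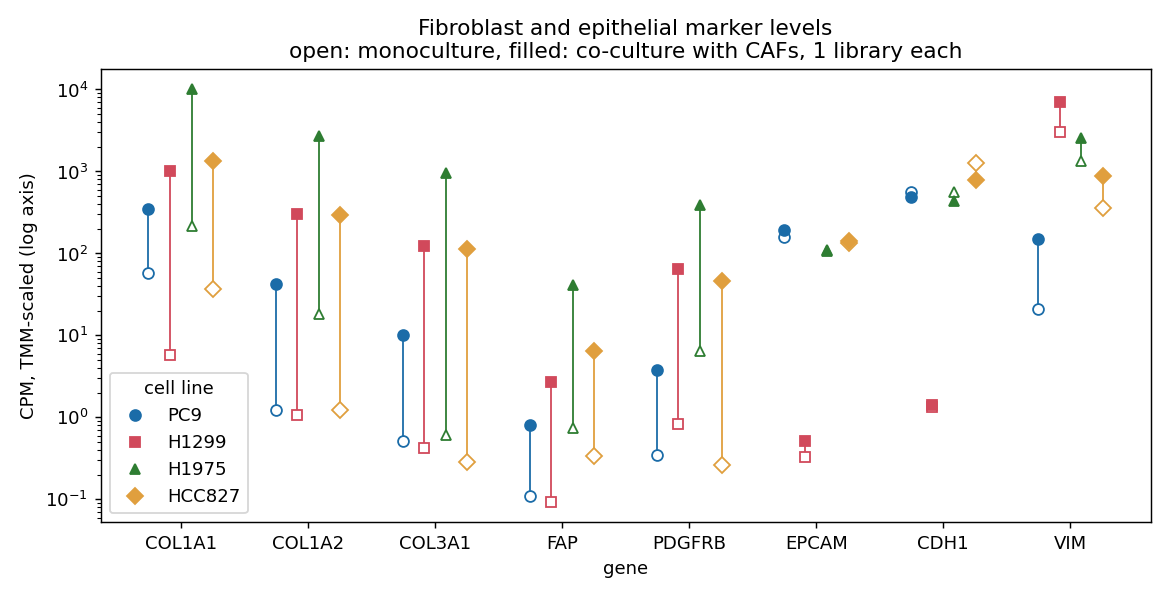
Level of each marker gene (horizontal axis) in CPM on a log axis, with 1 open symbol per monoculture library and 1 filled symbol per co-culture library, joined by a line for each cell line. COL1A1, COL1A2, COL3A1, FAP and PDGFRB are higher in co-culture in all 4 lines, while EPCAM in H1975 is at 111 and 108 CPM.

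The main comparison asked which genes the co-culture changed in the same direction in the 4 lines. Of 21650 genes tested, 17 rose and 3 fell. Collagens and other products of fibroblasts had the largest fold changes. PMEPA1 and SKIL, a pair of targets and restraints of TGF-beta signalling, rose from levels that all 4 lines already had when grown alone. Those that fell included CP and VTCN1. All 20 moved the same way in all 4 lines, although VTCN1 in H1299 and MEG8 in PC9 had too few reads to fix the direction there. Over all tested genes 29.4% did so, where chance gives 12.5%.

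COL1A2 (gene ID 1278, chromosome 7, 94394561 to 94431232, GRCh38.p13), the second chain of type I collagen, rose with a log2 fold change of 7.12 ± 0.60 (SE, n = 4 line pairs; edgeR adjusted p = 0.0357). Its level was 1.22, 1.08, 18.1 and 1.23 CPM in the monocultures of PC9, H1299, H1975 and HCC827 and 42.9, 302, 2683 and 293 CPM in the co-cultures. COL5A3, a type V collagen chain, rose by 6.11 ± 0.53 (edgeR adjusted p = 0.0357), CDH11, a mesenchymal cadherin, by 5.60 ± 0.60 (edgeR adjusted p = 0.0487), and FAP, the fibroblast activation protease, by 4.58 ± 0.49 (edgeR adjusted p = 0.0459). CD248, also called endosialin, a surface protein of fibroblasts and pericytes, had a log2 fold change of 7.15 ± 0.68 (SE; edgeR adjusted p = 0.0357), with 2 reads in the monoculture of PC9 against 37 in its co-culture, a ratio of 29.9 with an exact counting interval of 7.71 to 256. POSTN, the matrix protein periostin, had 1 read in each monoculture, so its log2 fold change of 9.02 ± 0.94 (SE; edgeR adjusted p = 0.0459) depends on the prior count. Its co-culture reads were 12 in PC9 (ratio 19.4, interval 2.87 to 829), 145 in H1299 (94.6, 16.7 to 3760), 3187 in H1975 (3470, 622 to 137000) and 176 in HCC827 (161, 28.6 to 6400). CDH11 had 3, 1 and 4 reads in the monocultures of PC9, H1299 and HCC827 against 23, 531 and 473 in their co-cultures, a ratio of 12.4 in PC9 (3.74 to 64.5) and 347 in H1299 (61.9 to 13700). Over all settings tried the lowest log2 fold change was 1.71 for CDH11, 1.17 for FAP, 1.95 for POSTN and 2.99 for CD248. All 6 were higher in all 4 co-cultures, as was the fibroblast share of reads, which counts COL1A2, CDH11, FAP and POSTN among its members.

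PMEPA1 (gene ID 56937, chromosome 20, 57648392 to 57711536, minus strand), a membrane protein induced by TGF-beta, rose by 3.07 ± 0.30 on the log2 scale (SE; edgeR adjusted p = 0.0357), from 271 to 2312 CPM in PC9, 292 to 1572 in H1299, 168 to 1080 in H1975 and 75.8 to 1305 in HCC827. On exon reads alone 11 of the 20 calls were kept. Those that did not pass included PMEPA1, with a log2 fold change of 3.385 (edgeR adjusted p = 0.0804; 1.22e-20 to 1 over all settings tried), SKIL (0.0576), IGFBP4 (0.0804), EDNRA (0.0716), FAP (0.0817), CD248 (0.0535) and VTCN1 (0.0535). SKIL (gene ID 6498, chromosome 3, 170357678 to 170396849), which encodes a co-repressor of SMAD proteins, rose by 1.93 ± 0.21 (SE; edgeR adjusted p = 0.0459), from 141 to 381 CPM in PC9, 27.9 to 148 in H1299, 34.6 to 175 in H1975 and 45.1 to 134 in HCC827. AMIGO2, a leucine-rich repeat adhesion molecule, rose by 1.95 ± 0.19 (edgeR adjusted p = 0.0357), IGFBP4, an insulin-like growth factor binding protein, by 1.69 ± 0.18 (edgeR adjusted p = 0.0459), EDNRA, an endothelin receptor, by 1.82 ± 0.20 (edgeR adjusted p = 0.0468), and MYL9, a myosin regulatory light chain of contractile cells, by 1.66 ± 0.15 (edgeR adjusted p = 0.0357). The remaining 5 that rose were chosen after their values were seen. CMTM3, a MARVEL-domain membrane protein, rose by 1.34 ± 0.12 (edgeR adjusted p = 0.0357), with log2 ratios of 1.33, 1.42, 1.31 and 1.31 in PC9, H1299, H1975 and HCC827. The other 4 are non-coding RNAs, NKILA (3.20 ± 0.28), LOC105372692 (2.92 ± 0.29), LOC107987300 (2.99 ± 0.26) and MEG8 (2.75 ± 0.24), each with an edgeR adjusted p = 0.0357. NKILA (chromosome 20, 57710183 to 57712780, plus strand) overlaps the start of PMEPA1 on the opposite strand, and LOC105372692 (57720481 to 57726375, plus strand) lies next to it. No strand setting of the counting was given in the sources used here, so the reads of NKILA and PMEPA1 cannot be assigned to either strand. MEG8 had 1 read in the PC9 monoculture and 5 in its co-culture, a ratio of 8.08 with an interval of 0.904 to 382.

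CP (gene ID 1356, chromosome 3, 149162410 to 149222045), the copper-carrying ferroxidase ceruloplasmin, had a log2 fold change of -2.85 ± 0.28 (SE; edgeR adjusted p = 0.0357). Its level was 139 CPM in the HCC827 monoculture and 12.5 in the co-culture, 5.39 and 0.924 in H1975, 1.83 and 0.431 in PC9 and 0.753 and 0.0768 in H1299. VTCN1 (chromosome 1, 117143587 to 117210985), an inhibitory ligand of T cells, had -2.36 ± 0.25 (SE; edgeR adjusted p = 0.0446) and went from 68.1 to 17.2 CPM in PC9, 15.6 to 1.99 in H1975 and 5.82 to 1.29 in HCC827. In H1299 VTCN1 had 3 reads in monoculture and 1 in co-culture (0.0706 and 0.0154 CPM), a ratio of 0.218 with an interval of 0.00414 to 2.71. The next smallest p among lower genes belonged to RAPGEF5 (-1.14 ± 0.13, edgeR adjusted p = 0.0558) and PPP1R12B (-0.97 ± 0.12, edgeR adjusted p = 0.0655), which did not pass the threshold.

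These calls come from edgeR's quasi-likelihood test with cell line as a block, so the spread tested was the disagreement between the 4 lines, and nothing in the labels says that a library stands for more than a single culture. Leaving out H1299, H1975 or HCC827 left 0 genes past the threshold (2699, 2726 and 4001 at an unadjusted edgeR p under 0.05, against 4119 with all lines), leaving out PC9 gave 15 higher and 1 lower, with 6 of the 20 calls kept, and DESeq2 called 877 higher and 795 lower with all lines.

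**Figure D2:**
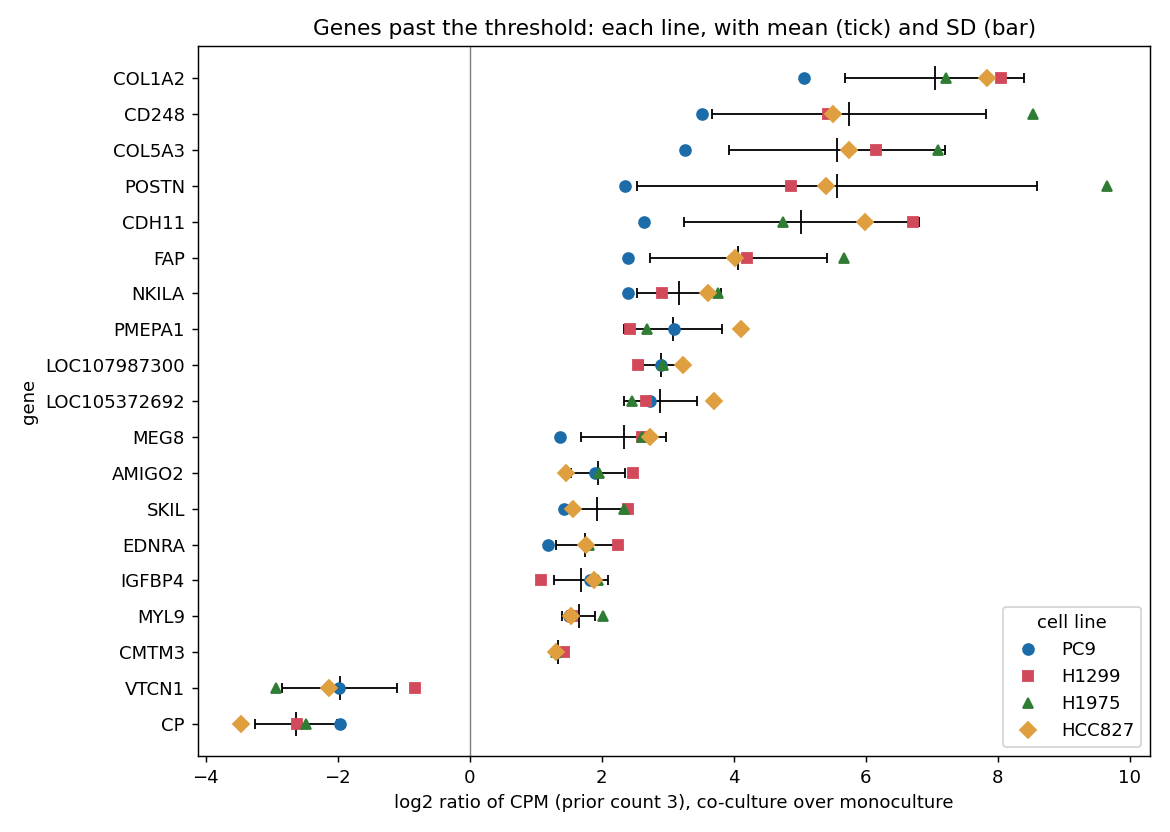
Log2 ratio of CPM, co-culture over monoculture, of the genes past the threshold that are reported here (vertical axis) in each cell line (1 symbol per line), with the mean as a black tick and the SD of the 4 lines as a bar. CMTM3 is between 1.31 and 1.42 in the 4 lines and COL1A2 between 5.07 and 8.05.

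The next comparison set the 32 gene lists fixed before the data were examined against all other genes, and camera with a preset correlation called 12 lists higher and 2 lower. None of the 14 held with an estimated correlation. That correlation was near the preset 0.01 for TGF-beta response (0.016), fibroblast-secreted factors (-0.003) and lung epithelial lineage (-0.027). Their unadjusted camera p still went from 3.06e-08 to 0.013, 0.00151 to 0.0414 and 0.0116 to 0.0757. Correlation between members therefore does not account for the loss of these calls. It was 0.031 to 0.91 in the other called lists. None passed with fry either, which tests a list against no change rather than against the other genes. After the culture labels were exchanged in 1 or 2 lines, which gives 7 other assignments, the same test called between 5 and 20 lists, so a call here is weak evidence that the lines moved together.

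In the fibroblast identity list, 22 of 24 members could be tested and all 22 had a positive log2 fold change, with a median of 4.87 (camera adjusted p = 2.95e-17; adjusted p = 0.317 with an estimated correlation). Of them 4 rose over all genes tested (COL1A2, FAP, POSTN and CDH11) and 17 adjusted over the list alone. In the contractile myofibroblast list, 7 of 9 were positive (camera adjusted p = 0.000848; adjusted p = 0.448 with an estimated correlation). MYL9 rose, 3 passed when adjusted over the list alone, and CALD1, which encodes caldesmon, had 1.33 ± 0.19 (SE; edgeR adjusted p = 0.0748). Of 18 fibroblast-secreted factors 13 were positive (camera adjusted p = 0.00371; adjusted p = 0.317 with an estimated correlation), 0 were called over all genes, and 5 higher and 2 lower adjusted over the list alone. GREM1, an antagonist of bone morphogenetic proteins, had 6.54 ± 0.97 (SE; edgeR adjusted p = 0.0902) and IL11, an interleukin of the IL6 family, 3.15 ± 0.66 (edgeR adjusted p = 0.126), whereas C3, the central complement protein, had -0.78 ± 0.14 (edgeR adjusted p = 0.0968).

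The TGF-beta response list had 15 of 17 members positive with a median of 1.14 (camera adjusted p = 2.45e-07; adjusted p = 0.317 with an estimated correlation). PMEPA1 and SKIL rose over all genes and 11 members adjusted over the list alone. SMAD7, an inhibitor of the pathway, had 1.24 ± 0.22 (SE; edgeR adjusted p = 0.0931). The mesenchymal transition list had 16 of 17 positive with a median of 1.40 (camera adjusted p = 1.94e-09; adjusted p = 0.317 with an estimated correlation), 0 called over all genes and 14 adjusted over the list alone. ITGA5, the fibronectin receptor subunit, had log2 ratios of 1.14, 1.16, 1.07 and 0.83 in PC9, H1299, H1975 and HCC827 (fitted 1.05 ± 0.13 SE; edgeR adjusted p = 0.0611). MSN, which links actin to the membrane, had 1.09 ± 0.20 (edgeR adjusted p = 0.0968), SNAI2, a repressor of epithelial genes, 2.83 ± 0.55 (edgeR adjusted p = 0.117) and VIM, the intermediate filament vimentin, 1.55 ± 0.32 (edgeR adjusted p = 0.124). In PC9, VIM went from 21.3 to 150 CPM. All these lists had positive medians in all 4 co-cultures, in which the fibroblast share of reads was also higher.

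Matrix proteases and inhibitors were positive in 16 of 18 (camera adjusted p = 7.69e-07; adjusted p = 0.317 with an estimated correlation), with 0 called over all genes and 12 higher and 1 lower adjusted over the list alone. ADAM12, a metalloprotease, had 1.67 ± 0.24 (SE; edgeR adjusted p = 0.0748), TIMP2, a metalloprotease inhibitor, 0.97 ± 0.16 (edgeR adjusted p = 0.0917), PLAU, the urokinase protease, 1.49 ± 0.27 (edgeR adjusted p = 0.0968) and MMP11 2.05 ± 0.44 (edgeR adjusted p = 0.127). Of 17 YAP and TEAD targets 14 were positive (camera adjusted p = 0.000113; adjusted p = 0.317 with an estimated correlation) and 6 passed adjusted over the list alone. TGFB2, a TGF-beta ligand, had 1.15 ± 0.21 (edgeR adjusted p = 0.10025), AXL, a receptor tyrosine kinase, 1.40 ± 0.28 (edgeR adjusted p = 0.120) and CCN2 2.10 ± 0.48 (edgeR adjusted p = 0.137). Laminins and basement membrane had 15 of 19 positive (camera adjusted p = 0.00112; adjusted p = 0.346 with an estimated correlation), 5 of them adjusted over the list alone. LAMA4, a laminin chain of mesenchymal cells, had 4.14 ± 1.10 (edgeR adjusted p = 0.161). Integrins and cell adhesion had 15 of 21 positive (camera adjusted p = 0.0023; adjusted p = 0.317 with an estimated correlation), 6 higher and 1 lower adjusted over the list alone. ITGAV, an integrin chain that takes part in activating TGF-beta, had 1.22 ± 0.17 (edgeR adjusted p = 0.0734), ITGB5 0.90 ± 0.15 (edgeR adjusted p = 0.0931) and CEACAM1 -1.52 ± 0.29 (edgeR adjusted p = 0.105). These lists too had positive medians in all 4 co-cultures, in which the fibroblast share of reads was higher. Their medians did not all follow the size of its rise. For YAP and TEAD targets the median was 0.752 in PC9, 0.711 in H1299, 0.52 in H1975 and 0.197 in HCC827. For laminins and basement membrane it was 0.925, 0.157, 0.531 and 0.534. With an estimate of fibroblast RNA, scaled from the H1975 co-culture, taken off, the median log2 ratios that remained in PC9, H1299 and HCC827 were 0.59, -0.11 and 1.20 for matrix proteases and inhibitors, 0.925, -0.50 and 0.19 for laminins and basement membrane, and 1.32, -0.34 and 0.87 for mesenchymal transition. They were 0.753, 0.60 and 0.03 for YAP and TEAD targets and 0.615, 0.18 and 0.37 for integrins and cell adhesion. The estimate also holds any reads that the H1975 cancer cells added, so a negative value shows no fall in the cancer cells.

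The proliferation lists were called higher by camera, unevenly between lines and with 0 members called over all genes. All 22 DNA replication genes were positive with a median of 0.75 (camera adjusted p = 9.93e-10; adjusted p = 0.575 with an estimated correlation), 20 of them in all 4 lines, and 16 passed adjusted over the list alone. The list median was 1.64 in H1299, 0.78 in HCC827, 0.41 in PC9 and 0.14 in H1975, and on exon reads 1.48, 0.745, 0.34 and 0.05. UHRF1, which maintains DNA methylation, had 1.09 ± 0.25 (SE; edgeR adjusted p = 0.132), MCM5, part of the replicative helicase, 0.95 ± 0.27 (edgeR adjusted p = 0.168) and CCNE1, cyclin E1, 0.73 ± 0.19 (edgeR adjusted p = 0.154), with log2 ratios of 0.81, 0.78, 0.76 and 0.55 in PC9, H1299, H1975 and HCC827. All 20 cell division genes were positive in the fit, 9 of them in all 4 lines (median 0.49; camera adjusted p = 1.14e-05; adjusted p = 0.715 with an estimated correlation), with 0 passing adjusted over the list alone, led by AURKB (0.86 ± 0.24, edgeR adjusted p = 0.166) and CDC20 (0.76 ± 0.22, edgeR adjusted p = 0.171). All 17 replication-dependent histone genes were positive in the fit, 4 of them in all 4 lines (median 0.65; camera adjusted p = 1.67e-05; adjusted p = 0.660 with an estimated correlation), 4 adjusted over the list alone. HIST1H4C had 1.07 ± 0.19 (edgeR adjusted p = 0.0968). In H1975 the median log2 ratio was -0.01 for cell division and -0.14 for histones, and on exon reads -0.17 and -0.32. Histone genes are near-identical copies, so how the counting split their reads is uncertain. In H1299, where these lists had their highest medians, the intron share of reads was 22.1% in monoculture and 13.5% in co-culture.

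Epithelial genes were lower in 19 of 21 members (median -0.45; camera adjusted p = 0.00206; adjusted p = 0.660 with an estimated correlation), 6 of them in all 4 lines. None was called over all genes, and 1 was higher and 3 lower adjusted over the list alone. CLDN3, a tight junction claudin, had -1.49 ± 0.29 (SE; edgeR adjusted p = 0.112) and the keratin KRT7 had 0.88 ± 0.24 (edgeR adjusted p = 0.163). ELF3, an epithelial transcription factor, went from 1251 to 396 CPM in HCC827 (edgeR adjusted p = 0.163 over the 4 lines). CDH1, the epithelial cadherin, went from 1256 to 794 CPM in HCC827, 566 to 431 in H1975 and 556 to 489 in PC9 and was at 1.34 and 1.43 CPM in H1299 (fitted -0.31 ± 0.16 SE; edgeR adjusted p = 0.347). Lung epithelial lineage genes were lower in 12 of 13 (median -0.64; camera adjusted p = 0.0266; adjusted p = 0.317 with an estimated correlation), 1 of them adjusted over the list alone. NAPSA, an aspartic protease of alveolar cells, had -0.80 ± 0.15 (edgeR adjusted p = 0.108). Without HCC827 the epithelial list no longer passed (camera adjusted p = 0.061), and the lung lineage list did not pass without HCC827 (0.147), without H1975 (0.171) or with a minimum of 100 reads (0.086). In the same co-cultures the share of reads in the fibroblast identity list was 4.29 to 18.1 times that of the monocultures. It reached 0.136% in PC9, 0.251% in H1299, 2.05% in H1975 and 0.312% in HCC827. The epithelial list medians there were -0.121, -0.391, -0.349 and -0.901. H1975, with the highest share, thus did not have the lowest median.

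The other 18 lists were not called. By camera adjusted p these were EGFR and MAPK output (0.152), unfolded protein response (0.234), interferon response (0.285), stem cell associated (0.318), acute phase and STAT3 (0.372), p53 targets (0.406), oxidative stress response (0.442), cholesterol synthesis and mesothelial markers (0.448 each), glycolysis (0.465), NF-kB response (0.502), endothelial markers (0.586), amino acid stress response (0.612), hypoxia and macrophage and leukocyte markers (0.772 each), desmosome and tight junction (0.825), and antigen presentation and pericyte and smooth muscle markers (0.828 each). Single members had the same sign in all 4 lines without passing edgeR's threshold. CCND1, cyclin D1, had 0.86 ± 0.15 (SE; edgeR adjusted p = 0.0931) and HBEGF, an EGFR ligand, 1.57 ± 0.28 (edgeR adjusted p = 0.0968). HMOX1, a haem oxygenase, had 1.56 ± 0.26 (edgeR adjusted p = 0.0931), GDF15, a stress cytokine, -1.47 ± 0.25 (edgeR adjusted p = 0.0931), IFIT1, an interferon-induced protein, -1.44 ± 0.22 (edgeR adjusted p = 0.078), and TJP3, a tight junction scaffold, -1.27 ± 0.19 (edgeR adjusted p = 0.0748).

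**Figure D3:**
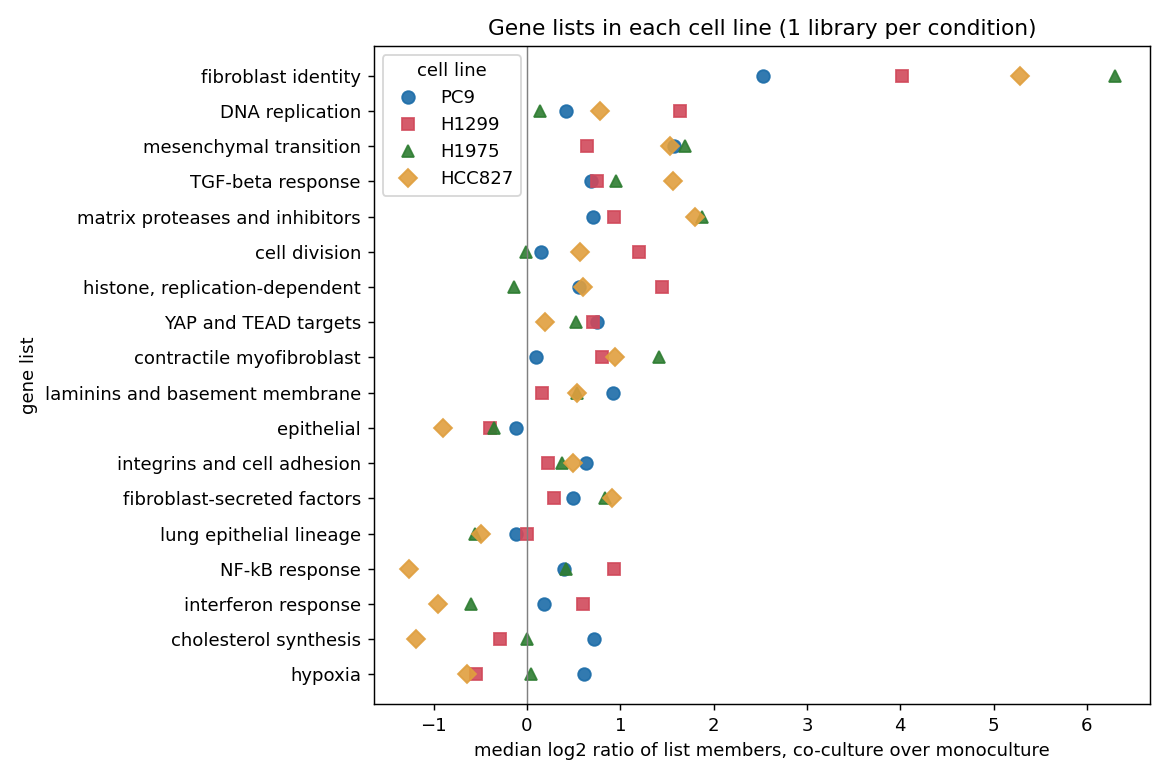
Median log2 ratio, co-culture over monoculture, of the members of the 14 called lists and of 4 lists whose medians went opposite ways (vertical axis), 1 symbol per cell line. Fibroblast identity lies between 2.53 and 6.30, and NF-kB response between -1.27 in HCC827 and 0.93 in H1299.

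Within each line the co-culture was set against its own monoculture, with 1 library each and so no test. PC9 had 264 genes higher and 134 lower by 4-fold or more, H1299 150 and 162, H1975 494 and 250, and HCC827 470 and 352. In PC9 the highest log2 ratios belonged to CGB8 (7.38) and CGB5 (6.30), copies of the chorionic gonadotropin beta gene whose near-identical sequences make the split of reads uncertain, PLXNA4, a semaphorin receptor (6.12, from 33 to 1574 reads), COL1A2 (5.07) and PTHLH, parathyroid hormone-related protein (4.73, from 2.68 to 72.7 CPM). The lowest were ATP6V1B1, a proton pump subunit (-4.43, from 59.5 to 2.71 CPM), FREM2 (-4.06), PALMD (-3.28), KRT4 (-3.27) and BMP3 (-3.18).

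In H1299 the 5 highest were collagens, COL1A2 (8.05), COL3A1 (8.03), COL4A2 (7.69), COL1A1 (7.46) and COL6A3 (7.34), and the lowest were ELAVL3, a neuronal RNA-binding protein (-3.41, from 19.6 to 1.80 CPM), LRRC7 (-2.56), ALDOC (-2.55), SFMBT2 (-2.36) and SOCS1, a suppressor of cytokine signalling (-2.26). In H1975 the highest were COL3A1 (10.50), POSTN (9.66), DCN, the proteoglycan decorin (9.64, from 3 to 4606 reads, a log2 interval of 9.16 to 12.99), GREM1 (9.42) and SULF1 (9.39). MUC16, the mucin known as CA-125, had the lowest ratio there (-3.48, from 830 to 74.6 CPM), and among the next were TREM1 (-3.24), ZBTB7C (-3.20) and VTCN1 (-2.94).

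In HCC827 the highest were COL3A1 (8.38), COL1A2 (7.83), COL6A3 (7.66), PDGFRB (7.17) and MMP9, a gelatinase (7.08, from 0.967 to 138 CPM). The lowest ratio belonged to SFTPA1, a surfactant protein, which went from 117 to 0.174 CPM (-9.00, 6189 to 10 reads), with a near-identical copy, SFTPA2, that makes its reads uncertain. KRT20, a keratin of gut epithelium, went from 89.3 to 0.452 CPM (-7.46), GPA33 from 13.8 to 0.156 CPM (-6.04), CYP26A1, which degrades retinoic acid, from 16.2 to 0.295 CPM (-5.54), and PIGR, the receptor that carries antibodies across epithelium, from 76.2 to 1.89 CPM (-5.29). KRT20 was not lower in any other line.

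The similarity of the lines was taken as the Spearman correlation of their log2 ratios across genes, which are not independent replicates, so no p is given. The 6 pairs of lines gave a median of 0.275, from 0.143 for H1299 and HCC827 to 0.437 for H1299 and H1975. In a count chosen after seeing the data, 96 genes were higher by 2-fold or more in all 4 lines, where 0.36 would be shared if the lines were independent, and 51 were lower, where 1.59 would be. The 96 include COL1A1, COL1A2, COL3A1, FAP and PDGFRB of the fibroblast identity list, so they are not a count of responses of the cancer cells. The expected counts treat all genes alike. Among the 51 are genes with few reads, such as CNDP1 and AWAT1 (means of 0.187 and 0.282 CPM), whose ratios vary more.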

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

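The test of TGF-beta genes on exon reads and the test on PMEPA1 and SKIL were chosen after their results were seen. The values for matrix and adhesion lists after fibroblast RNA was taken off were also picked for this section after they were seen. The other tests were not.

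Of 64 sets of 4 values examined, 6 held a value far from the other 3, where chance gives about 1 in 20, or 3.2 sets. The intron share of reads was 22.5% in the HCC827 co-culture, far above the other 3 co-cultures and also above the highest monoculture, at 22.1%. MEG8 had its lowest log2 ratio in PC9, at 1.36, where it rests on 1 and 5 reads. IGFBP4 had its lowest in H1299, at 1.08, and MYL9 its highest in H1975, at 2.02. CMTM3 had its highest in H1299, at 1.42, in a gene whose 4 ratios spread over an SD of only 0.05. The mesenchymal transition list had its lowest median in H1299, at 0.64. Its member VIM was at 3032 CPM in that line grown alone and at 7097 CPM in co-culture.

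A further 4 lists had medians of at least 0.5 in opposite directions in different lines, a difference that was not tested, with 1 library per line and condition. NF-kB response had a median log2 ratio of 0.93 in H1299 and -1.27 in HCC827, 2.195 apart. Cholesterol synthesis had 0.72 in PC9 and -1.19 in HCC827, 1.91 apart. Interferon response had 0.60 in H1299 and -0.96 in HCC827, 1.55 apart, and hypoxia 0.61 in PC9 and -0.65 in HCC827, 1.26 apart. Among 10000 random lists matched on expression the higher of each pair stood at percentile 100 and the lower at 0. The lists were picked for medians of that size, which makes extreme percentiles likely in advance. Random lists also draw genes independently. The estimated correlation between members was 0.481 for NF-kB response, 0.825 for cholesterol synthesis, 0.544 for interferon response and 0.539 for hypoxia. The percentiles therefore add no support. On exon reads alone, a setting added after seeing the data, the medians kept these signs, 0.64 and -0.81 for NF-kB response and 0.65 and -1.07 for cholesterol synthesis.

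The first pattern weighed is the rise of fibroblast identity genes. If fibroblast RNA in the co-culture libraries were the source, the added reads of the list's members should stand in a similar order in every line. The median Spearman correlation of the added CPM across the 22 members was 0.866 over the 6 pairs of lines (0.654 to 0.945), against 0.325 for the median of 1000 random lists matched on expression and 0.61 for the upper end of their central 95%. The values go with fibroblast RNA as a source. They do not single it out, because a rank correlation compares the order of members and not their proportions. The random lists were matched on expression but not on how far genes rose. Proportions varied between lines. COL3A1 gained 9.54 CPM with 291 CPM of COL1A1 in PC9 and 124 with 1015 in H1299. In H1975 it gained 968 with 9866, and in HCC827 113 with 1293. Abundant members such as COL1A1, at 10080 CPM in the H1975 co-culture, and COL1A2, at 2683, were in the added reads. Of the 22 members 16 were already at 1 CPM or more in at least 1 monoculture, so a response of the cancer cells themselves stays open and was not tested.

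The second pattern is the rise of TGF-beta response genes. An effect of intron reads as the whole cause is argued against by exon reads alone. On these the list median was 0.606 in PC9, 0.581 in H1299, 1.413 in H1975 and 1.512 in HCC827. The list had an adjusted camera p of 2.12e-06 on exon reads (on all gene reads, 6.9e-08 to 2.78e-06 with a line left out and adjusted p = 0.317 with an estimated correlation). Camera also called lists after culture labels were exchanged, so that p adds little. Fibroblast RNA was estimated by scaling all reads added in H1975, the co-culture with the highest fibroblast share, to the fibroblast identity genes of the other lines by the median of their scales, or by the upper quartile as a larger estimate, which assumes the same fibroblast profile in each. For the list as a whole the lowest remaining median log2 ratio was 0.343, in H1299, with a bootstrap interval of -0.602 to 0.717 (0.323 with the upper quartile), so for the list fibroblast RNA cannot be told apart from a response of the cancer cells, since the interval spans 0. For PMEPA1 and SKIL the lowest ratio that remained with the upper quartile was 1.34 (SKIL in HCC827), and the PC9 co-culture gained 2041 CPM of PMEPA1 with 291 CPM of COL1A1, where H1975 gained 912 with 9866, which argues against RNA of fibroblasts with the same profile as the whole cause for these 2 genes, while a response of cancer cells, or of CAFs that differed by line, remains open.

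With the same estimate taken off at the median of the members' scales, the median of the matrix protease list went from 0.71 to 0.59 in PC9, 0.94 to -0.11 in H1299 (bootstrap interval -2.637 to 0.822) and 1.80 to 1.20 in HCC827. That of laminins and basement membrane was 0.925 before and after in PC9, and went from 0.16 to -0.50 in H1299 (-1.697 to 0.157) and 0.53 to 0.19 in HCC827. That of mesenchymal transition went from 1.575 to 1.32 in PC9, 0.64 to -0.34 in H1299 (-0.593 to 0.311) and 1.53 to 0.87 in HCC827. YAP and TEAD targets went from 0.71 to 0.60 in H1299 (0.212 to 0.803) and 0.20 to 0.03 in HCC827, and were 0.753 before and after in PC9. Integrins and cell adhesion went from 0.63 to 0.615 in PC9, 0.225 to 0.18 in H1299 (-0.791 to 0.602) and 0.49 to 0.37 in HCC827.

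With the upper quartile of the scales, the medians that remained in PC9, H1299 and HCC827 were 0.432, -0.121 and 0.734 for matrix proteases (intervals -0.053 to 0.986, -2.608 to 0.795 and -0.165 to 1.798). They were 0.607, -0.941 and 0.191 for laminins and basement membrane (0.357 to 1.521, -2.923 to -0.056 and -0.342 to 1.121), and 0.994, -0.35 and 0.639 for mesenchymal transition (0.241 to 1.729, -0.613 to 0.283 and 0.296 to 1.367). For YAP and TEAD targets they were 0.753, 0.585 and 0.024 (0.431 to 1.321, 0.16 to 0.798 and -0.425 to 0.343), and for integrins and cell adhesion 0.599, 0.169 and 0.35 (0.427 to 0.912, -0.791 to 0.602 and -0.989 to 0.547). The fibroblast identity list itself was left at -0.754, -1.072 and -1.522, against -0.008, -0.055 and 0.251 with the median scale. The upper quartile thus took off more than that list had gained. Either estimate also holds any reads that the H1975 cancer cells added. A negative remainder therefore shows no fall in the cancer cells.

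The third pattern is the higher level of DNA replication genes, most in H1299. H1975, with the highest fibroblast share, had a median of 0.14, against 1.64 in H1299. This argues against RNA of fibroblasts with the same profile as the whole cause. The median that remained in H1299 after fibroblast RNA was taken off was 1.63. Its bootstrap interval was 1.468 to 1.754 over members with an estimated correlation of 0.86. The estimate taken off was scaled from the reads added in H1975, so the 1.63 restates the low H1975 median and is no separate test. On exon reads the median in H1299 was 1.48, which argues against the fall in intron share as the whole cause there, while that in H1975 was 0.05. Without H1299 the list was still called (camera adjusted p = 8.2e-08, from 3.73e-13 to 7.17e-07 when another line was left out). With all lines it was not called by camera with an estimated correlation (adjusted p = 0.575). Nor did it pass with fry, which tests it against no change (fry adjusted p = 0.233). Culture density was not given in the sources used here and was not tested, and a response to co-culture stays a hypothesis.

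The splits of the libraries that part all 4 line pairs number 8, too few for a share under 0.05. The real split gave 17 genes higher and the highest of the others 0 (1 of 8 splits with as many), and 3 lower against 0 (1 of 8). For the lists, the real split gave 12 higher and the highest other 20 (3 of 8), and 2 lower against 20 (8 of 8). These other splits exchange the culture labels within 1 or 2 lines. The 24 splits that part only 2 pairs, which mix lines with cultures, gave 0 genes by edgeR and up to 17 lists.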

How the results depend on the processing

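Exon reads alone were added after seeing the data, and all other settings were set beforehand. The 17 genes higher and 3 lower were unchanged with RLE size factors and with scaling without the fibroblast lists, each with all 20 calls kept, and unique reads gave 18 and 3, also with all 20. The share of reads in fibroblast identity genes changed by a mean log2 of 3.02 to 3.71 with a line left out and 2.39 without its 3 most abundant members. The similarity of the lines, 0.275, was 0.32 and 0.273 in its alternatives. The counts became 877 higher and 795 lower with DESeq2 (52.5% higher, against 85%), 95 and 47 with limma-voom (66.9%), 206 and 116 with no low-count filter (64%), and 8 and 1 with a minimum of 100 reads. They were 1 and 0 on log2(TPM + 0.5), and 0 and 0 on log2(TPM + 1), with 2622 and 2494 genes at an unadjusted limma p under 0.05. Exon reads gave 9 higher and 3 lower, with 11 of the 20 calls kept. The fit with no replicate block gave 0 and 0, with 356 at an unadjusted edgeR p under 0.05, since differences between lines then count as error. Leaving out each line gave 0 to 15 higher and 0 to 1 lower, in fits with fewer libraries.

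Lists called went from 12 higher to 0 with an estimated correlation and 0 with fry, and from 2 lower to 0 with either, 0 with no replicate block, 1 with a minimum of 100 reads and 0 to 5 with a line left out. The counts of fry answer another question, since it tests a list against no change. With no replicate block the epithelial list (camera adjusted p = 0.371) and the lung lineage list (0.353) did not pass. Interferon response was called lower on exon reads (camera adjusted p = 0.0349), without PC9 (0.0419) and without H1299 (0.000912), and lay between 0.086 and 0.911 in the other settings, with an upward direction without HCC827 (0.756). Other lists were also called only with a line left out. Without PC9 these were cholesterol synthesis (camera adjusted p = 0.000483) and hypoxia (0.0315), both lower. Without HCC827 15 lists were higher, with NF-kB response (0.00211), EGFR and MAPK output (0.00826) and unfolded protein response (0.00211) added.

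In single lines, a minimum of 10 CPM gave 116 genes higher and 38 lower in PC9, 52 and 19 in H1299, 205 and 49 in H1975, and 192 and 153 in HCC827. Genes lower numbered 86 in H1299 with a prior count of 10, 69 in H1299 and 106 in H1975 among protein-coding genes, and 101 and 151 on exon reads. The protein-coding setting and the 10 CPM minimum count fewer genes by construction. For the other settings the cause was not tested.

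Over 115 named gene values none reversed. These were the called or smallest-p genes of the main fit, the markers, and list members at an unadjusted edgeR p under 0.05. Genes chosen this way are unlikely to reverse when the same reads are fitted again. In 119 comparisons a value newly passed a threshold, 72 of them with DESeq2, and in 107 it no longer did, 47 of them with a line left out. PMEPA1 had a log2 fold change between 2.72 and 3.43 over the settings, with an adjusted p of 1.22e-20 to 1. Where a count moved with another test or filter, the cause was not tested.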

Other observations

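The test on the intron share of the added TERT reads was chosen after the TERT reads were seen, with its limit on length set after the values for genes of any length were seen, and the other test of TERT was not. The genes named here were chosen after their values were seen, among those higher by 2-fold or more in all 4 lines. INHBA, an activin subunit, had log2 ratios of 1.20, 5.53, 6.57 and 5.73 in PC9, H1299, H1975 and HCC827 (fitted 4.95 ± 1.10 SE; edgeR adjusted p = 0.132). TGFBI, a TGF-beta-induced matrix protein of the TGF-beta list, had 1.54, 3.03, 2.57 and 5.33 (3.06 ± 0.62; edgeR adjusted p = 0.125). NRP2, a receptor of semaphorins, had a log2 fold change of 1.68 (edgeR adjusted p = 0.0537), TNFRSF12A, a receptor of the TNF family, 1.56 (0.0655), and NOG, an antagonist of bone morphogenetic proteins, 2.23 (0.0819). MT2A, a metallothionein, had 1.78 (0.0537) and SPHK1, a sphingosine kinase, 1.92 (0.0734). None of these 7 genes passed edgeR's threshold.

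TERT, the catalytic subunit of telomerase, was also higher by 2-fold or more in all 4 co-cultures, with log2 ratios of 2.74, 1.60, 4.55 and 3.42 in PC9, H1299, H1975 and HCC827 (fitted 3.15 ± 0.51 SE; edgeR adjusted p = 0.0917). Its level went from 0.314 to 2.41 CPM in PC9, 8.84 to 26.9 in H1299, 1.13 to 27.8 in H1975 and 1.02 to 11.5 in HCC827. The intron share of its reads went the other way, from 40% to 20% in PC9 (20 and 95 reads; exact intervals 19.1 to 63.9 and 12.5 to 29.5), 60.1% to 43.4% in H1299, 54.4% (41.9 to 66.5) to 9.2% (7.8 to 10.7) in H1975 and 59.3% to 15.6% in HCC827. A candidate explanation is a TERT coding sequence without introns, as is used to immortalise fibroblasts, and the labels name no such step. It would need the intron share to fall to under 0.5 of the monoculture share in all 4 lines, and the highest of the 4 ratios was 0.722, in H1299, with 0.5 in PC9, 0.169 in H1975 and 0.263 in HCC827. The reads added per 1000 CPM of added COL1A2 were 50.3, 60, 10 and 35.8 CPM in PC9, H1299, H1975 and HCC827. Exon reads of TERT went from 12 to 76 in PC9, 150 to 991 in H1299, 31 to 1396 in H1975 and 22 to 558 in HCC827. The intron share of whole libraries went from 15.8% to 13.1% in PC9, 22.1% to 13.5% in H1299, 20.9% to 13% in H1975 and 16.8% to 22.5% in HCC827, and in H1299 it fell by a larger factor than that of TERT. Its intron reads also rose, from 8 to 19 in PC9 (3.84-fold in CPM, exact interval 1.6 to 10.1), 226 to 760 in H1299 (2.19, 1.89 to 2.56), 37 to 141 in H1975 (4.15, 2.87 to 6.13) and 32 to 103 in HCC827 (2.95, 1.97 to 4.53). They made up 17% of the added reads in PC9 (6.9 to 27.4), 35.2% in H1299 (30.7 to 39.5), 7.3% in H1975 (5.6 to 8.9) and 11.3% in HCC827 (7.7 to 14.9). Genes without an annotated intron also hold some reads counted as intron. Among 117 such genes of between 0.5 and 2 times the exon length of TERT, the upper end of the central 95% was 4.2%, 3.9%, 3% and 4.5% in the same co-cultures. The lower bound for TERT lay at least 2.56 percentage points above it in every line, which argues against a sequence without introns as the whole cause. Among all 206 such genes, short ones included, that upper end was 17.1%, 16.6%, 16.1% and 15.5%, which only H1299 exceeded. In H1975 and HCC827 the intron percentages of the added reads lay below the monoculture shares of 54.4% (41.9 to 66.5) and 59.3% (45 to 72.4). This argues against more reads of the cells' own gene at an unchanged intron share as the whole rise there. PC9 and H1299 lie between the bounds set in advance for the share. As a part of the rise, an introduced sequence cannot be told apart from more transcription of the cells' own gene with a lower intron share, which was not tested.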
